A study of Aspergillus luchuensis with 15 samples.

How the data were processed

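The series measured RNA of the white koji mold Aspergillus luchuensis (named Aspergillus kawachii in the labels), strain SH46, growing on steamed barley. Per the labels' protocols, barley polished to 70% with 35% water uptake was taken from 36 °C up to 40 °C over the first 25 h, and was then either lowered to 30 °C or kept at 40 °C. Batches of 100 g koji were made in triplicate, and the series' design text says that each experiment used separate koji, so the 3 arrays of a group are independent cultures. RNA came from 2 g of crushed koji, and 50 ng of it was labelled with Cy3 and hybridised to a 1-colour Agilent array. The 15 arrays form 5 groups of 3, and each sample's group and replicate number came from its title.

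The deposited scanner files hold spot intensity values made by the authors with Agilent Feature Extraction 10.7, per the submitters' processing notes (10.7.1.1, per the file headers). Per the file headers, the processed intensity is background-corrected for each spot and not scaled between arrays. The value table by the authors gives a single intensity per probe and array on a linear scale, and how it was made is not given in the sources used here. Each of its columns ranked the probes as that array's median spot signal did (Spearman rho 1), and its column medians ran from 282.03 to 283.32. Its values therefore look scaled between arrays without background subtraction. In each column 80.3% to 82.8% of the values were multiples of 1/48. The sorted values of the other arrays differed from those of the first array by a median of 0.16 to 0.33. Averaging sorted signals over the series' arrays alone would not favour multiples of 1/48, so arrays outside the series may have entered that scaling. The method is not given, so this stayed unproven, and the table served as an alternative only.

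The array carried 62838 spots, of which 1319 were control spots and were left out. The other 61519 probes named 11486 gene tags, 10734 of them with 5 probes each. A further 316 tags had more than 5 probes, up to 20. Spots flagged as outliers (39 over all arrays) were set to missing, and 0 of the probes were saturated. The main values were log2 of the processed signal minus the array's 75th percentile over non-control probes. A probe was kept when it was well above background on all 3 arrays of at least 1 group (50364 probes), and a gene's value was the median of its kept probes. This left 10468 genes, and 1018 tags had no kept probe. The 75th percentile of the signal ranged from 389 to 1876 between arrays, and 69.9% to 82.9% of probes were well above background. The number of arrays limits the precision.

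All 15 arrays entered 1 linear model with a mean per group (limma 3.58.1 in R 4.3.3, lmFit and eBayes), which gives every comparison a shared estimate of each gene's spread. The model had 10 residual degrees of freedom and 3.45 prior degrees of freedom. The 7 comparisons were 30 °C against 40 °C at 26.5 h and at 44 h, the difference between those, 26.5 h against 25 h for each temperature, and 44 h against 26.5 h at each temperature. Adjusted p is limma's p after the Benjamini-Hochberg correction over the genes of a comparison, with a threshold of 0.05. The comparisons, thresholds and alternatives listed below were fixed before the data were examined. The R package data.table (version 1.17.8) read the files, and Python 3.11.15 with matplotlib 3.10.9 and pandas 2.3.3 drew the plots.

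Arrays were simulated with each gene's real mean over all arrays and the model's spread for that gene, the same in every group. The wider spread of the 44 h 40 °C group was thus not simulated. The fit was tested on these arrays of 10468 genes, with 200 changed genes per comparison. For 30 °C against 40 °C at 26.5 h, it recovered 87.9% of genes changed 4-fold, 31.3% of those changed 2-fold and 0 of 67 changed 1.41-fold. At 44 h, it recovered 83.3% of 4-fold and 26.9% of 2-fold changes, and for the difference between times 63.6% and 1.49%. Each rate rests on 66 or 67 genes, so the small gaps between 26.5 h and 44 h were not read as differences between the times. The real data had far more than 200 genes past the threshold, 1942 at 26.5 h and 4417 at 44 h. Adjusted p depends on how many genes change, so these rates need not hold for the real comparisons.

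Genes appear by tag. None (0) of the 11486 tags matched the RefSeq gene table (12941 genes, assembly AkawachiiIFO4308_assembly01) on any locus tag, older tag or synonym, and the scanner files do not pair tags with names. The 24 gene lists and the panel of named enzymes and heat-shock proteins fixed beforehand were therefore not tested. For each comparison of 2 groups, the text names the 2 largest rises and 2 largest falls among genes past the threshold whose 3 arrays of one group all lay above the 3 of the other. A gene was ranked only if at least 1 array of each group had a probe well above background. No genes were ranked for the difference between times, where that separation has no meaning. Means are given on the log2 scale relative to the array's 75th percentile, with the SD over 3 arrays.

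The file headers place the arrays on 2 slides, scanned separately. Slide 1 held the 25 h arrays, the 26.5 h 30 °C arrays and replicates 1 and 2 of the 44 h 30 °C group. Slide 2 held replicate 3 of that group, the 26.5 h 40 °C arrays and the 44 h 40 °C arrays. Comparisons were repeated with slide as a fixed block and, where a slide held both groups, within the slide. At 26.5 h each temperature lay on 1 slide, so the slide term there rested on 44 h 30 °C replicate 3 alone.

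Deviations from the group means of same-numbered arrays were correlated across genes to see whether the replicate numbers pair the arrays. Only for 26.5 h 40 °C against 25 h 40 °C did all 3 pairs exceed 0.1 (0.26, 0.39 and 0.635), from the data alone, since the labels tie no numbers across groups. In both groups the 75th percentile of the signal rose with the replicate number. It was 954, 1254 and 1695 at 25 h, and 802, 1150 and 1876 at 26.5 h and 40 °C. Pairing and signal strength were not told apart here.

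The alternatives were normexp (offset 50), quantile normalization, median centring, the authors' table, no filter and a stricter filter on dim probes, the brightest probe per gene, trended robust eBayes, only the arrays compared, replicate and slide blocks, each array left out, and other thresholds. The files used here hold no mean spot signal, so normexp used the median spot signal and its local background.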

Results

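Gene expression of the white koji mold Aspergillus luchuensis was measured in barley koji before and after a change of temperature control. The first group was sampled at 25 h, when the koji had reached 40 °C. From then on the koji was either lowered to 30 °C or kept at 40 °C, and both were sampled at 26.5 h and 44 h. Each of the 5 groups had 3 arrays. The 75th percentile of the signal was 954 to 1695 in the 25 h arrays, 850 to 1381 and 802 to 1876 in the 26.5 h arrays at 30 °C and 40 °C, and 389 to 1348 and 591 to 1758 in the 44 h arrays at 30 °C and 40 °C. Of 10468 genes tested, 9393 (44 h, 30 °C) to 10009 (25 h) had a probe well above background on all 3 arrays of a group. Replicate arrays correlated across genes with r of at least 0.962 in 4 groups, and of 0.904 to 0.964 in the 44 h 40 °C group.

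The first principal component held 45.9% of the variance and set the 44 h arrays apart from the earlier ones. The second held 29.3% and ordered the 25 h arrays, the 26.5 h 40 °C arrays and the 26.5 h 30 °C arrays. The median gene's SD between replicates was 0.43 log2 units in the 44 h 40 °C group, against 0.18 to 0.29 in the others. Its 3 arrays were spread over components 1 and 2, with replicate 1 nearest to the 26.5 h arrays. The spread shared between groups in the model may therefore understate the error of comparisons that use the 44 h 40 °C group.

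**Figure D1:**
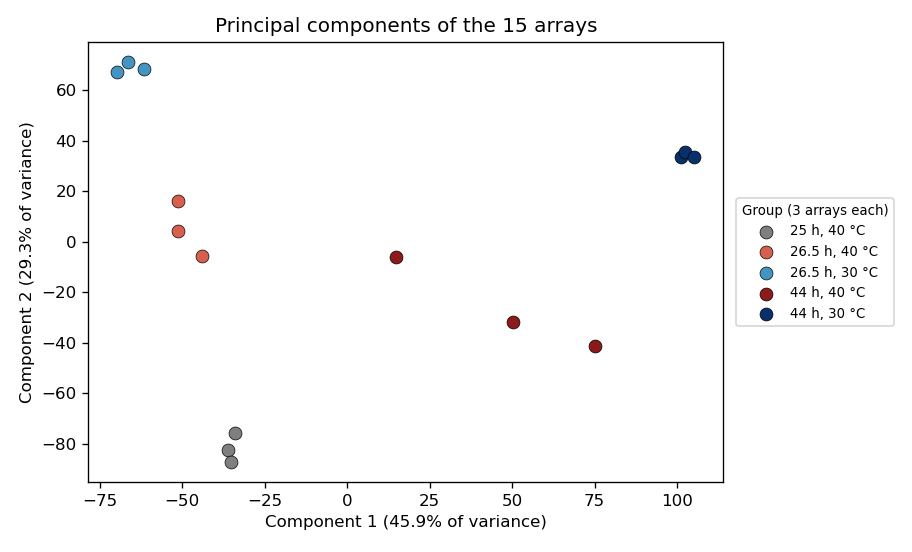
Scores of the 15 arrays on principal components 1 (45.9% of variance) and 2 (29.3%) of the log2 values of 10468 genes, coloured by group with 3 arrays each. The 26.5 h 40 °C arrays lie between the 25 h arrays and the 26.5 h 30 °C arrays, and the 44 h 40 °C arrays are the most spread.

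Lowering the temperature for 1.5 h, against keeping it, addressed the early response to the lower setting. At 26.5 h, 1076 genes were higher and 866 lower at 30 °C than at 40 °C, of which 749 and 535 differed at least 2-fold. AKAW_11338 was 23.7-fold higher at 30 °C (log2 level 4.88 ± 0.78 against 0.31 ± 0.26, SD, n = 3; log2 difference 4.57, SE 0.36, limma adjusted p = 7.53e-06). AKAW_00173 was 23.8-fold higher (-1.14 ± 0.25 against -5.72 ± 0.17; adjusted p = 0.00748). AKAW_01484 was 25.7-fold lower (-4.25 ± 0.40 against 0.44 ± 0.59; SE 0.41, adjusted p = 1.75e-05) and AKAW_11124 was 21.9-fold lower (-4.57 ± 0.75 against -0.12 ± 0.90; SE 0.57, adjusted p = 1.55e-04). All 5 probes of each of these 4 genes went the same way. The 3 arrays of one group lay above the 3 of the other in 45.6% of all genes, where chance gives 10%, and in 1931 of the 1942 genes past the threshold. In 43 of the 1942 genes 1 group had no array well above background.

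Each temperature at 26.5 h was on 1 slide, so no value within a slide exists. With slide as a block, 115 genes were higher and 84 lower, and AKAW_00173 (log2 difference 3.62, adjusted p = 0.385; range over its alternatives 2.01e-04 to 0.385) and AKAW_11124 (-3.60, adjusted p = 0.101; range 4.43e-05 to 0.101) no longer passed, while AKAW_11338 (4.84, adjusted p = 0.00914; range 1.65e-06 to 0.00914) and AKAW_01484 (-4.12, adjusted p = 0.0214; range 4.34e-06 to 0.0214) did. The count fell to 1213 without 26.5 h 30 °C replicate 2, to 1251 without 26.5 h 40 °C replicate 1, and to 1158 with normexp background correction. It rose to 2790 with the spread from the 6 arrays compared alone, and quantile normalization turned the majority, with 886 higher and 951 lower. The log2 differences of AKAW_00173 (4.58), AKAW_01484 (-4.68) and AKAW_11124 (-4.46) shrank to 2.81, -3.61 and -3.29 with normexp, and to 2.39, -3.44 and -3.10 in the authors' table.

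The same comparison after 19 h at either setting addressed the later state. At 44 h, 2227 genes were higher and 2190 lower at 30 °C than at 40 °C, 1465 and 1321 of them at least 2-fold. AKAW_10058 was 95.2-fold higher at 30 °C (-0.23 ± 0.19 against -6.80 ± 0.96, SD, n = 3; SE 0.45, adjusted p = 7.11e-07), with 2 of the 3 arrays at 40 °C well above background; its log2 difference was 6.57 here, 3.55 with normexp and 3.41 in the authors' table. AKAW_10977 was 74.1-fold higher (4.17 ± 0.45 against -2.04 ± 2.70; SE 1.02, adjusted p = 4.47e-04), with a wide spread at 40 °C. AKAW_11124, among the largest falls at 26.5 h, was 46.8-fold lower at 30 °C (-2.29 ± 0.65 against 3.26 ± 1.13; SE 0.57, adjusted p = 1.51e-05). AKAW_04358 was 37.5-fold lower (-1.94 ± 0.09 against 3.29 ± 0.37; SE 0.29, adjusted p = 2.37e-07). Its log2 difference at 26.5 h was -4.18. The arrays of the groups were separated in 43.2% of all genes and in 3903 of the 4417 past the threshold, and in 187 of these 1 group had no array well above background.

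**Figure D2:**
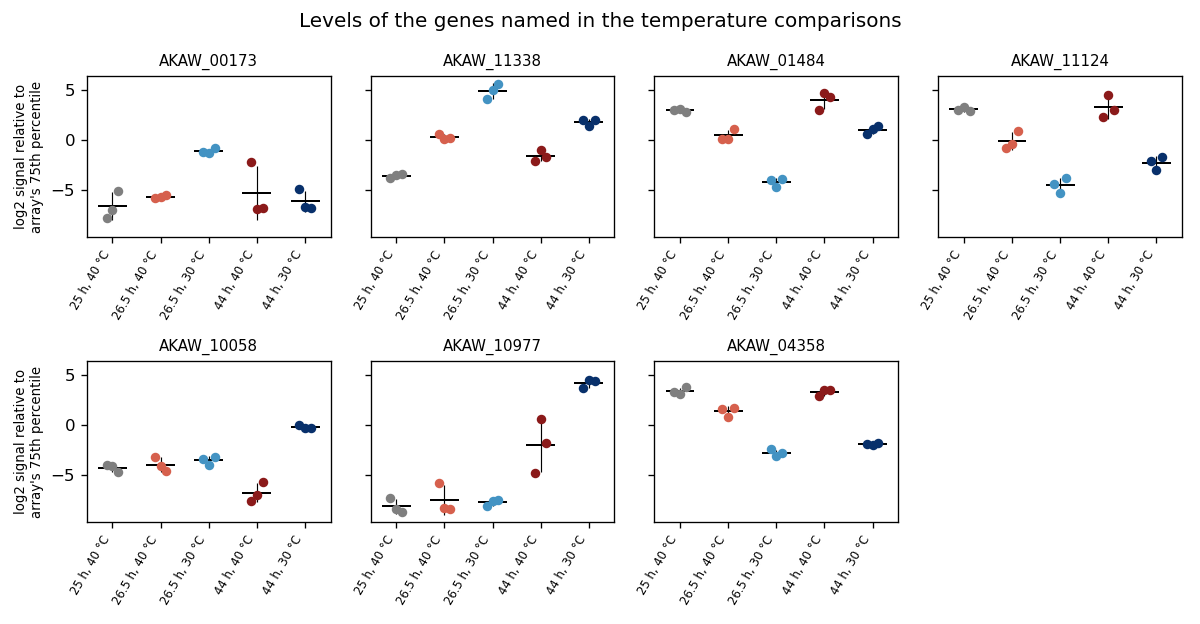
Levels of the 7 genes named in the 2 temperature comparisons, as log2 signal relative to each array's 75th percentile, in the 5 groups; points are the 3 arrays of a group, horizontal lines their mean and vertical lines 1 SD. AKAW_04358, AKAW_11124 and AKAW_01484 lie lower at 30 °C than at 40 °C at both times, and AKAW_11338 higher, while AKAW_10058 and AKAW_10977 part at 44 h.

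The 44 h split between rises and falls moved with the background correction, to 1832 higher and 988 lower with normexp. The fit blocked on slide gave 1242 genes higher and 1049 lower at 30 °C. Within slide 2, which held 1 of the 30 °C arrays, 341 were higher and 188 lower, and AKAW_10977 did not pass there (adjusted p = 0.0807, range over its alternatives 1.76e-05 to 0.0807), although its log2 difference was 6.41 there against 6.21 with all 15 arrays. Without the dim 44 h 30 °C replicates 2 and 3 the count was 1780, and with the spread taken from the 6 arrays compared alone it was 2123, fewer than the 2790 that such a fit gave at 26.5 h. Which time had more genes thus depended on the spread used, while the root mean square log2 difference between temperatures, sampling error removed, was 0.78 at 26.5 h and 0.98 at 44 h.

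Whether the early and late temperature differences involved the same genes was tested by their overlap. Of the genes higher at 30 °C at 26.5 h, 437 were also higher at 44 h, where independent lists would share 229 (odds ratio 2.90, 95% interval 2.54 to 3.32; Fisher's exact test, 2-sided, p = 1.29e-52, adjusted over 8 overlaps 1.72e-52). Of those lower, 380 were also lower, against 181 (odds ratio 3.37, 2.91 to 3.89; exact p = 1.83e-57, adjusted 2.93e-57). Another 101 went from higher to lower and 97 from lower to higher, fewer than the 225 and 184 that independent lists would share. Across genes, which are not independent replicates, the 2 sets of log2 differences correlated with r = 0.32 and rho = 0.30, and the comparisons shared no array. Slide 1 held all 30 °C arrays at 26.5 h and 2 of the 3 at 44 h, while slide 2 held all 40 °C arrays. A slide difference could thus enter both comparisons with the same sign and add to the overlaps and the correlation. The exact test does not allow for this. In the fit blocked on slide the lists were shorter, with 115 genes higher and 84 lower at 26.5 h, and 1242 and 1049 at 44 h. Shorter lists share fewer genes, so a smaller overlap there does not by itself show less sharing. The overlaps were 48 and 43 genes in that fit, and 212 and 225 with normexp. Without 1 array they ranged from 265 and 252 (26.5 h 30 °C replicate 2) to 682 and 545 (44 h 40 °C replicate 1), and the first was 289 without 26.5 h 30 °C replicate 3, 281 without 26.5 h 40 °C replicate 1 and 282 without 26.5 h 40 °C replicate 3.

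**Figure D3:**
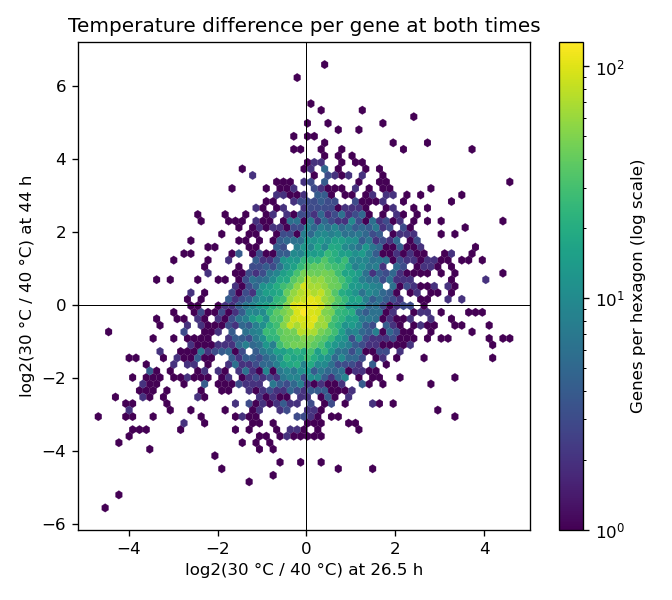
Number of genes (colour, log scale) by their log2 ratio of 30 °C over 40 °C at 26.5 h (horizontal) and at 44 h (vertical), for 10468 genes with 3 arrays per group. The cloud leans upward, with r = 0.32 across genes, and holds genes that differ at 1 time alone.

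The temperature difference itself changed between the times in 2248 genes, in 1082 of them upward and in 1166 downward at 44 h. The log2 difference had opposite signs at the 2 times in 1522 of these, values near 0 included, and was larger in size at 44 h in 69.3%. Choosing genes by a changed difference by itself favours opposite signs. Only 198 passed the threshold between temperatures at both times in opposite directions, and 109 at both in the same direction. Another 1363 passed at 44 h alone, 452 at 26.5 h alone and 126 at neither time. AKAW_10058 differed by 0.42 log2 units at 26.5 h (adjusted p = 0.571) and by 6.57 at 44 h, a change of 6.16 (SE 0.64, adjusted p = 6.09e-05). AKAW_10977 changed by 6.46 (SE 1.45, adjusted p = 0.0072). AKAW_00173 changed by -5.42 (SE 1.46, adjusted p = 0.0193), and its difference was -0.84 at 44 h (adjusted p = 0.534). Its levels at 44 h were low, -6.19 ± 1.04 at 30 °C and -5.35 ± 2.73 at 40 °C. At 40 °C replicate 1 stood at -2.20, and replicates 2 and 3 at -6.97 and -6.89. For AKAW_11338, AKAW_01484, AKAW_11124 and AKAW_04358, the change between times did not pass the threshold. With normexp, 763 genes changed upward and 358 downward, and quantile normalization gave 1209 and 982. The blocked fit gave 834 and 880, and without the dim 44 h 30 °C replicates 2 and 3 the count was 918.

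The same 1.5 h without a change of setting gave the passage of time at 40 °C. Between 25 h and 26.5 h at 40 °C, 1862 genes rose and 1930 fell. AKAW_05814 rose 71.1-fold (from -4.79 ± 0.25 to 1.37 ± 0.12; SE 0.41, adjusted p = 9.76e-07) and AKAW_05924 rose 64.2-fold (from -5.78 ± 0.27 to 0.23 ± 0.26; adjusted p = 9.16e-06). AKAW_05040 fell 33.8-fold (from 1.08 ± 0.18 to -4.0 ± 0.91; adjusted p = 2.15e-05) and AKAW_08357 fell 25.6-fold (from -1.78 ± 0.14 to -6.45 ± 1.56, with 2 of 3 arrays well above background; adjusted p = 1.32e-04). The arrays were separated in 3744 of the 3792 genes past the threshold. These groups were on separate slides. In the blocked fit, 433 genes rose and 457 fell, and the 4 genes passed with adjusted p of at most 0.0183. The excess of falls was wider with quantile normalization (1600 rose, 1985 fell), median centring (1628 and 2224) and the authors' table (1402 and 1944). With normexp, 1326 rose and 1319 fell. The log2 changes of AKAW_05814 (6.15), AKAW_05924 (6.0), AKAW_05040 (-5.08) and AKAW_08357 (-4.68) shrank to 4.92, 4.14, -4.13 and -2.34 with normexp, and to 4.43, 3.57, -3.81 and -2.07 in the authors' table.

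When the koji was lowered to 30 °C instead, 2749 genes rose and 2455 fell over the same interval. AKAW_00497 rose 426-fold (from -5.67 ± 0.48 to 3.06 ± 0.31; SE 0.94, adjusted p = 4.32e-06) and AKAW_05814 rose 371-fold (to 3.75 ± 0.38; adjusted p = 7.69e-09). AKAW_10296 fell 260-fold (from 2.50 ± 0.14 to -5.53 ± 0.41, 3 probes; adjusted p = 7.34e-08) and AKAW_07792 fell 225-fold (from 5.49 ± 0.06 to -2.33 ± 0.41; adjusted p = 1.77e-08). Separation held in 5173 of the 5204 genes past the threshold. Both groups were on slide 1, where the slide's arrays alone gave 3116 rises and 2720 falls; the blocked fit gave 2686 and 2412. Falls outnumbered rises with quantile normalization (2328 rose, 2720 fell), median centring (2382 and 2862) and the authors' table (2272 and 2651). For AKAW_00497 (8.73), AKAW_05814 (8.53) and AKAW_10296 (-8.02), the log2 changes were 6.95, 7.15 and -6.06 with normexp, and 6.46, 6.73 and -5.61 in that table.

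Both courses shared most of their changed genes: 1629 rose and 1606 fell in both, and 15 moved in opposite directions, where independent lists would share 489 and 453. The changes correlated with r = 0.86 across genes, with 0.50 from simulated unchanged groups against the same 25 h arrays. The covariance was 1.35 against a simulated 0.06, and part of the excess in the overlap may come from the shared 25 h arrays. After the simulated terms were subtracted, the slope of the change at 40 °C on the change at 30 °C was 0.58. AKAW_05814 rose by 6.15 log2 units at 40 °C and by 8.53 at 30 °C. AKAW_11338 rose by 3.92 and 8.49, and the log2 changes of AKAW_11124 were -3.16 and -7.62. With sampling error removed, the 26.5 h 40 °C group lay at 57.8% of the way from the 25 h group to the 26.5 h 30 °C group (54.7% to 60.3% when each array was left out).

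**Figure D4:**
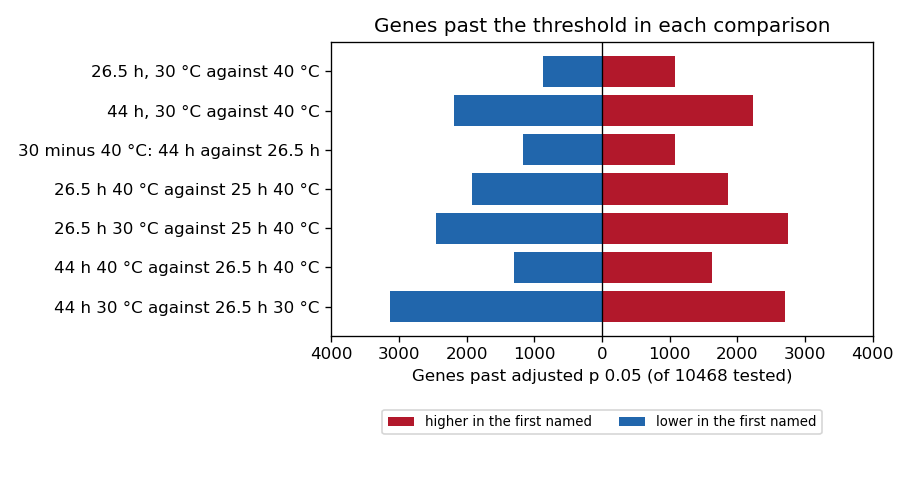
Number of genes past an adjusted p of 0.05 in each of the 7 comparisons, of 10468 tested with 3 arrays per group; bars to the right are genes higher in the group named first, bars to the left are genes lower. The comparison of 44 h with 26.5 h at 30 °C has the most, 2705 higher and 3130 lower.

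Later development was compared at each setting. From 26.5 h to 44 h at 40 °C, 1627 genes rose and 1301 fell. AKAW_08653 rose 427-fold (from -6.23 ± 0.59, with 2 of 3 arrays well above background, to 2.50 ± 2.28; SE 0.78, adjusted p = 3.70e-06) and AKAW_05040 rose 284-fold (from -4.0 ± 0.91 to 4.15 ± 1.29; adjusted p = 2.65e-07). AKAW_10307 fell 39.7-fold (from 4.20 ± 0.54 to -1.11 ± 0.28; adjusted p = 1.87e-07). AKAW_10057 fell 31.1-fold by the median of its 5 probes (adjusted p = 2.30e-07), but its probes ranged from -5.27 to -0.49 log2 units, and by its brightest probe it did not pass (adjusted p = 0.376, range over its alternatives 1.60e-07 to 0.376). The groups' arrays were separated in 33.5% of all genes and in 2607 of the 2928 past the threshold. With the spread from these 6 arrays alone, which are all on slide 2, 878 genes rose and 446 fell. The blocked fit gave 1564 and 1219. The excess of rises was not kept by quantile normalization (1421 rose, 1606 fell), median centring (1480 and 1520) or the authors' table (1301 and 1438). Log2 changes of AKAW_08653 (8.74), AKAW_05040 (8.15) and AKAW_10057 (-4.96) were 6.41, 7.12 and -1.80 with normexp, and 5.98, 6.93 and -1.68 in the authors' table.

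At 30 °C, 2705 genes rose and 3130 fell over the same interval. AKAW_10977 rose from -7.78 ± 0.34 to 4.17 ± 0.45, by 11.96 log2 units (SE 1.02, adjusted p = 5.25e-07), and AKAW_10408 rose from -5.77 ± 0.59 to 4.25 ± 0.17 (SE 0.39, adjusted p = 6.90e-10). AKAW_04135 fell 270-fold, from 1.76 ± 0.13 to -6.32 ± 0.44 (adjusted p = 1.11e-07), though its 5 probes ranged from -8.18 to -4.93 log2 units and the brightest gave -5.18, and AKAW_06000 fell 127-fold, from 0.46 ± 0.41 to -6.53 ± 0.66 (adjusted p = 2.43e-05). Of the 5835 genes past the threshold, 5699 had separated arrays. With normexp, 2725 rose and 1880 fell, and the log2 changes shrank to 8.18 for AKAW_10977, 7.84 for AKAW_10408 (from 10.01), -4.80 for AKAW_04135 and -3.65 for AKAW_06000; in the authors' table they were 7.64, 7.44, -5.15 and -3.98. With slide as a block, 2438 rose and 2740 fell, and within slide 1, which held 2 of the 44 h arrays, 2708 rose and 3227 fell.

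The changes from 26.5 h to 44 h at the 2 temperatures shared no array and correlated with r = 0.76 and rho = 0.64 across genes. At both temperatures 1226 genes rose, against 420 for independent lists (odds ratio 15.2, 95% interval 13.4 to 17.3), and 1014 fell, against 389 (odds ratio 11.8, 10.2 to 13.6). Opposite changes were called in 58 and 33 genes. AKAW_05040 rose at both temperatures, and the difference between its rises was -2.34 log2 units (30 °C minus 40 °C, adjusted p = 0.0436). AKAW_10408 rose 3.57 more at 30 °C (adjusted p = 8.49e-04). For AKAW_04135 the same difference was -3.47 (adjusted p = 0.0104), but its level fell at both temperatures. It went from 1.76 ± 0.13 to -6.32 ± 0.44 at 30 °C and from -1.19 ± 0.16 to -5.79 ± 1.73 at 40 °C. Both groups thus ended low, and at 26.5 h it had been 2.95 log2 units higher at 30 °C.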

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

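The tests of the slides below, and the splits with the common difference taken out, were chosen after the result was seen; the tests of signal strength and the remaining splits were not. The temperature difference at 44 h differed from that at 26.5 h in 2248 genes by limma's test of the difference. Among the named genes the log2 change was -5.42 for AKAW_00173, 6.16 for AKAW_10058, 6.46 for AKAW_10977, -2.34 for AKAW_05040, 3.57 for AKAW_10408 and -3.47 for AKAW_04135. Of 100 splits that exchanged temperature labels within times, 1 (the real one) gave as many as its 1728 genes on the 12 arrays, and the highest other gave 1238, but such splits test for no temperature difference at either time. With the difference common to both times taken out of each gene, which tests for an unchanged difference, the highest other gave 301. The real split alone reached its count, the lowest share that 100 splits allow, which argues against chance. At an unadjusted p under 0.05 the gap was smaller, 3456 genes against 2517. The splits do not address the slide, which coincided with temperature at 26.5 h.

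Comparisons of 3 against 3 arrays have 10 splits, too few for a share under 0.05; in each, the real split was the 1 split with as many genes. On the arrays compared alone, limma called 2790 genes between temperatures at 26.5 h, 2123 at 44 h, 4665 and 6308 from 25 h to 26.5 h at 40 °C and 30 °C, and 1324 and 6043 from 26.5 h to 44 h. The highest of the 9 other splits was 0 in each, with 779, 626, 594, 317, 1293 and 374 genes at an unadjusted p under 0.05. For 26.5 h against 25 h at 40 °C, where same-numbered arrays deviated alike, 3 of the other splits part as many pairs.

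The first pattern weighed is the 1942 genes that differed between 30 °C and 40 °C at 26.5 h, where each temperature was on 1 slide. A slide difference alone, unrelated to the change from 25 h to 26.5 h at 30 °C on slide 1, would leave the 40 °C arrays at 100% of that change; they lay at 57.8%, and at most at 60.3% with an array left out, which argues against the slide as the whole cause. A difference in signal strength explained 0.278% of the variance of the log2 differences at 26.5 h, where the groups' log2 75th percentiles differed by -0.12. It explained more where the dim 44 h 30 °C arrays entered. The share was 8.27% between temperatures at 44 h (difference -0.74) and 3.66% from 26.5 h to 44 h at 30 °C (-0.86). With slide as a block the median size of the difference in the 1942 genes was 1.22 log2 units before and 1.22 after. The median SE rose from 0.27 to 0.50. Log2 differences of all genes before and after correlated with r = 0.88, so estimates of single genes moved as well as their precision. The bridging array, 44 h 30 °C replicate 3, differed from replicates 1 and 2 with a slope of -0.009 on the log2 differences. A slide difference alone would give -1, but this is a single array. How many single genes a slide difference may have added stays open. Although 199 genes passed with the block, its slide term rests on that array, so the temperature itself stays open as well.

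The second pattern is the place of the 26.5 h 40 °C arrays between the 25 h arrays and the 26.5 h 30 °C arrays. A slide difference alone, unrelated to that line, would leave them at 0% of it, against 57.8% (at least 54.7% with an array left out). The change from 25 h predicted by signal strength ran against the observed one, with r = -0.16 across genes (2.58% when squared). The array that bridges the slides, 44 h 30 °C replicate 3, differed from replicates 1 and 2 with a slope of -0.04 on that change, where a slide difference alone would give 1, but it is a single array. A hypothesis is that a change under way at 25 h went on at both settings and may have gone further at 30 °C. The 1.5 h of time and the setting were not separated further.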

How the results depend on the processing

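The single-slide fits, the averaging of probe copies and the fit without dim arrays were chosen after the data were seen. Across 454 fits of the 24 named gene results, none reversed, 449 stayed past the threshold and 5 did not. These results were picked as the largest changes past the threshold in the same arrays. Most were thus likely to pass again, and the counts say little about other genes. Under the stricter filter on dim probes only 18 of the 24 results could be fitted, since the other genes had no value left. Quantile normalization, median centring, the authors' table, both filters, the brightest probe, trended robust eBayes and averaged probe copies kept every count within 1.5 times. So did the replicate block, with 1762, 4169, 2034, 3601, 5040, 2738 and 5670 genes in the order of the plot of counts; it changed no call of a named gene. The cause was not tested except where given.

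With normexp, the counts were 1158 and 2820 between temperatures at 26.5 h and 44 h and 1121 for the difference between times, and the overlaps 212 and 225. Normexp also moved the median of all genes by 0.23 log2 units at 44 h, 0.21 for the difference between times and 0.31 from 26.5 h to 44 h at 30 °C. From 25 h to 26.5 h at 30 °C, quantile normalization moved it by -0.14, median centring by -0.14 and the authors' table by -0.11. Quantile normalization moved it by -0.10 from 26.5 h to 44 h at 40 °C, and median centring by 0.12 for the difference between times. Each shift was far below the named changes, but whether rises or falls were more numerous turned with the scaling in several comparisons.

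With slide as a block, the counts were 199 and 2291 between temperatures and 890 from 25 h to 26.5 h at 40 °C, and the overlaps 48 and 43; the block widened the standard errors. Slide 2 alone gave 529 between temperatures at 44 h, with 1 array at 30 °C assumed to vary like the others, and 1324 from 26.5 h to 44 h at 40 °C. Only the arrays compared gave 2123 and 1324 for these, and 2790 between temperatures at 26.5 h, so the order of the 2 times turned. Without the dim 44 h 30 °C arrays, the counts were 1780 at 44 h and 918 for the difference between times, with overlaps of 226 and 218, from a single 30 °C array.

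Leaving out each array gave 1213 to 1696 genes at 26.5 h between temperatures (lowest without 26.5 h 30 °C replicate 2, then 1251 without 26.5 h 40 °C replicate 1), and kept the other comparisons within 1.5 times. The overlaps ranged from 265 to 682 (higher at 30 °C) and from 252 to 545 (lower). The first moved by over 1.5 times without 26.5 h 30 °C replicates 2 (265) and 3 (289), 26.5 h 40 °C replicates 1 (281) and 3 (282) and 44 h 40 °C replicate 1 (682), and the second without 26.5 h 30 °C replicate 2. A 2-fold minimum gave 1284, 2786 and 2406 genes for the temperature comparisons and 25 h to 26.5 h at 40 °C, and overlaps of 265 and 209. An adjusted p under 0.01 gave 1010, 2612, 986, 2317 and 1659 for the temperature comparisons, their difference, and the intervals at 40 °C, and overlaps of 172 and 168. Gene list tests, with preset or estimated correlation, were not run, since no list could be filled. Signal over background limits the dimmest genes: the rise of AKAW_10977 from 26.5 h to 44 h at 30 °C ranged from 7.64 to 12.22 log2 units.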

Other observations

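The test at tags 2 apart was chosen after a first one, at tags 5 apart, had been seen; that of the arrays' deviations was not. Over all genes, at each temperature, the 44 h group was no nearer to the 25 h group than the 26.5 h group was. The root mean square log2 distance from 25 h, sampling error removed, was 1.51 at 26.5 h and 1.74 at 44 h at 30 °C, and 0.98 and 1.12 at 40 °C. Named genes with large early falls went both ways. AKAW_10296 stood at 2.50 ± 0.14 at 25 h, -5.53 ± 0.41 at 26.5 h and 2.14 ± 0.57 at 44 h at 30 °C, and at -1.53 ± 1.02 and 5.07 ± 1.07 at 26.5 h and 44 h at 40 °C. AKAW_08357 stood at -1.78 ± 0.14 at 25 h and -1.88 ± 0.54 at 44 h at 30 °C. AKAW_11124 (3.05 ± 0.22, -4.57 ± 0.75 and -2.29 ± 0.65 at 25 h, 26.5 h and 44 h at 30 °C) and AKAW_04358 (3.37 ± 0.34, -2.82 ± 0.32 and -1.94 ± 0.09) stayed low.

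Without 44 h 40 °C replicate 1, 4378 genes were called from 26.5 h to 44 h at 40 °C, against 2928 with all arrays. Without replicate 2 of that group, 1969 were called. Of the 1942 genes called between temperatures at 26.5 h, 198 were called the opposite way at 44 h. That was fewer than independent lists would share: 101 against 225 from higher to lower, and 97 against 184 from lower to higher.

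Genes with neighbouring tag numbers changed together. The log2 temperature difference at 44 h correlated with r = 0.15 between next tags (9687 pairs), where the highest of 1000 shuffles of the tags gave 0.04; at 26.5 h it was 0.18. One gene split over 2 tags would leave nothing between tags 2 apart, where r was 0.0695 (highest shuffle 0.03), so this argues against split genes as the whole cause; 5 apart, r was 0.02 and within the shuffles. Errors shared by neighbouring tags cannot be told apart from joint regulation, since deviations of single arrays from their group means correlated between next tags with a median r of 0.10 (0.02 to 0.16), 64.0% of that at 44 h, and those deviations hold differences between cultures too. Joint regulation of neighbouring genes is a hypothesis, and no biological explanation was tested, since the tags were not paired with genome positions here.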
